A study of Mus musculus with 6 samples.

How the data were processed

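Gene expression was measured in total RNA from dorsal skin or skin tumours of C57BL6/129Sv mice with 6 one-colour Illumina BeadChip arrays, 1 sample per array. Per the labels' protocols, the shaved backs of 8-week-old mice received 10 µg of DMBA, dissolved in 100 µl acetone, every week over 18 to 20 weeks, or 100 µl of the solvent alone. RNA was extracted with an RNeasy Mini kit and checked on a Bioanalyzer, and biotinylated cRNA was made with the Ambion MessageAmp kit, per the labels. The 4 groups were wild-type (WT) acetone skin with 1 array, WT DMBA tumour with 2 arrays, STING-deficient (SKO) acetone skin with 1 array and SKO DMBA skin with 2 arrays. Replicate numbers follow accession order and pair nothing across groups. The labels number the samples without saying that each came from a different mouse, so p-values measure the spread between these samples, which may be technical.

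The deposited non-normalized table holds, per the file headers and the values, a linear probe intensity and a detection value for each of 45281 probes on each array. The scanner, its software and any background step are not given in the sources used here. The deposited detection p-values are headed as p-values, yet they rise with the signal (Spearman correlation of at least 0.975 on every array), so 1 minus the deposited value was used as the detection p. The authors also deposited a matrix of processed values. Against the intensities, these deposited log2 values were the log2 of quantile-normalized signals without background correction, minus each probe's median over the 6 arrays, with a mean absolute difference of at most 0.00125. Their column medians were -0.00263 for WT acetone skin, 0.0122 and 6.82e-05 for the tumours, -0.000698 for SKO acetone skin, and -0.00172 and -0.00292 for SKO DMBA skin. Scale, centring and direction of the matrix were all found this way, and the matrix served as an alternative only.

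Signals were background-corrected from the detection p-values, quantile-normalized and put on the log2 scale with neqc of limma 3.58.1 (R 4.3.3) with an offset of 16. The platform annotation named 1 gene for 34885 probes, several for 18 and none for 10378; a probe without a listed gene is unnamed here, and no gene was named from a probe with several. Symbols were updated through gene identifiers with a RefSeq table of assembly GRCm38.p6, which held the identifier of 34807 of the one-gene probes. Each gene was represented by its probe with the highest mean over the 6 arrays, and 11997 of 19057 genes whose probe had a detection p under 0.01 on at least 1 array were tested. The detected probes per array numbered from 16086 on WT tumour 1 to 19628 on SKO DMBA skin 2, and the number of arrays limits the precision.

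The 4 group means were fitted to all 6 arrays with lmFit and eBayes of limma. The model has 2 residual degrees of freedom, all from the groups of 2, and eBayes added 2.45 prior degrees of freedom. The lone acetone arrays were assumed to vary like the groups of 2. The contrasts were WT tumour minus WT acetone skin, SKO DMBA skin minus SKO acetone skin, WT tumour minus SKO DMBA skin, and the difference of the first pair of responses. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The acetone arrays of the genotypes were compared without a test, and a list's median there was set against 10000 random lists of the same size matched on mean expression. SE is limma's moderated standard error.

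The 27 gene lists, the tests, the rule for named genes and all other settings except those named last were fixed before the data were examined. The lists held 822 entries, of which 750 were on the array and 660 were tested. They covered interferon-stimulated genes, inflammatory cytokines and chemokines, cytosolic DNA sensing and STING signalling, hyperproliferative and wound keratinocyte genes, epidermal differentiation, basal keratinocyte and hemidesmosome, hair shaft and hair follicle, sebaceous gland, adipocyte, skeletal muscle, cell cycle, macrophage and monocyte, neutrophil, T and NK cell, B cell and plasma cell, antigen presentation and dendritic or Langerhans cell, mast cell, fibroblast and extracellular matrix, matrix proteases and invasion, endothelium, melanocyte, AhR, NRF2 and xenobiotic metabolism, p53 targets and DNA damage response, RAS-MAPK output and EGFR ligands, hypoxia and glycolysis, erythrocyte, and Schwann cell and nerve. Some genes stand in more than 1 list, S100a8, S100a9 and Lcn2 in both the neutrophil and the hyperproliferative list, and skin expresses members of most lists. Each list was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. These p-values were adjusted over the lists within a contrast. List members were counted over all tested genes and with p adjusted over the list alone.

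Named genes were the targeted gene, the 10 largest rises and falls past the threshold, or up to 5 of the largest values each way where fewer than 5 passed, and in each list up to 2 members with the largest positive and 2 with the largest negative difference. For WT tumour, SKO DMBA skin and the genotype comparison, every replicate had to lie on the same side of the other group. Predicted or clone symbols were not named. Where a gene was not detected on any array of the dimmer group, only a bound is given, as at least N-fold: the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest detected signal and the probe's own signal.

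The procedure was tested on 11997 independently simulated genes. For WT tumour minus WT acetone skin, 54.6% of genes changed by 4 log2 units and 0.299% of those changed by 2 passed, and for WT tumour minus SKO DMBA skin 77.3% and 3.28% passed. For the difference of responses 0 genes changed by 4 passed, while 95.8% had an unadjusted p under 0.05. Camera with the preset correlation called 15 of 15 lists shifted by 1 log2 unit and 0 of 108 unshifted lists, and with an estimated correlation it called 0 of 15.

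Alternatives were no background correction, an offset of 50, equal medians or no normalization between arrays, the authors' deposited matrix, other detection filters (no filter, at least 2 arrays, all 6 arrays), the mean of a gene's detected probes, every detected probe, trended or robust eBayes, the groups compared alone, a 2-fold minimum, an adjusted p under 0.10, an estimated correlation and leaving out each DMBA array. No slide block was run, as no slide is given. Chosen after the data were seen were the WT acetone array as control for SKO DMBA skin, the comparison of all 3 SKO with all 3 WT arrays, the raising of undetected signals to 1 limit, the highest of the arrays' lowest detected signals, and the 20 simulated sets of unchanged arrays, with spreads drawn from the eBayes prior, that were set beside the overlap of the responses.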

Results

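Transcript levels were measured in dorsal skin and skin tumours of wild-type (WT) mice and of mice lacking STING (SKO), an endoplasmic reticulum adaptor that passes the signal of cytosolic DNA to interferon and NF-κB responses. The skin had been painted with DMBA, a carcinogenic polycyclic aromatic hydrocarbon, or with acetone, its solvent. WT acetone skin and SKO acetone skin were represented by 1 array each, WT DMBA tumours by 2 and SKO DMBA skin by 2. DMBA-treated WT samples were tumours and DMBA-treated SKO samples were skin, so genotype and kind of tissue changed together. Between 35.5% and 43.3% of the 45281 probes were detected per array. Differences are log2 units of normalized intensity with limma's SE unless stated otherwise.

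The SKO DMBA arrays resembled each other (r = 0.981 across genes, which are not independent replicates) and 390 of 11997 genes lay over 2-fold apart between them. The tumours resembled each other less (r = 0.923), with 1831 genes over 2-fold apart. Tumour 2 lay closer to SKO DMBA skin 2 (r = 0.939, 1738 genes over 2-fold apart) than to tumour 1, although the tumours are averaged as 1 group below. Skeletal muscle genes had a median difference from WT acetone skin of -7.06 in tumour 1 and -2.22 in tumour 2, hair genes -5.50 and -1.50, and interferon-stimulated genes -0.57 and 0.85. Tumour 1 did not detect 29 of 33 muscle genes and 23 of 30 hair genes, so their values there are limits. Genes of the hyperproliferative keratinocyte list lay high in both, at 4.07 and 3.61.

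Sting1, the targeted gene, was represented by the probe ILMN_2736197, which was detected on 4 of 6 arrays. Before normalization its intensity was 144.5 in WT acetone skin, 85.7 in tumour 1 and 155.8 in tumour 2. In SKO acetone skin it was 91.7, and in SKO DMBA skin 108.5 and 99.7. The probe was not detected in tumour 1 or in SKO acetone skin. WT tumour minus SKO DMBA skin was 0.64 (SE 0.51, n = 2 and 2, limma adjusted p = 0.423), and without tumour 2 it was -0.046. WT tumour minus WT acetone skin was -0.21 (SE 0.62), and without tumour 1 it was 0.48. Where the probe lies relative to the deleted part of the gene is not given in the sources used here, so these values do not check the genotype labels.

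WT tumours were compared with WT acetone skin to find the transcripts that set a DMBA tumour apart from solvent-treated skin. Genes of wounded and hyperproliferative epidermis rose. Of 34 measured members, 31 were positive with a median of 4.15. With p adjusted over the list alone, 23 rose and 0 fell (camera adjusted p = 2.23e-15, 0.422 with an estimated correlation). Sprr2d, which encodes a small proline-rich protein of the cornified envelope, rose by 8.06 (SE 0.94) and its relative Sprr2e rose at least 179-fold, both adjusted over the list alone. The simple-epithelium keratin Krt8, which tumour 2 did not detect, and the envelope precursor Ivl had differences of -0.53 (SE 0.92) and -0.04 (SE 0.39).

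Epidermal differentiation genes moved both ways in the tumours. Of 39 members, 9 rose and 3 fell adjusted over the list alone (median 0.58, camera adjusted p = 0.00334, 0.668 with an estimated correlation). Lce3c, a late envelope gene of damaged epidermis, rose by 7.93 (SE 0.77) and Rptn, which encodes repetin, by 5.74 (SE 0.35), adjusted over the list alone. By the same test Krt77, not detected in tumour 1, changed by -5.73 (SE 1.10) and the envelope gene Lce1m by -3.97 (SE 0.53). Without either SKO DMBA array, left out 1 at a time here and in what follows, 4 epidermal genes rose and 1 fell. Basal keratinocyte and hemidesmosome genes had a median of 0.03 and 0 of 18 passed (camera adjusted p = 0.338). Without tumour 1, 4 rose and 2 fell adjusted over the list alone, and without tumour 2, 7 rose and 1 fell. The list was called upward with equal medians (0.13) and without normalization between arrays (0.010), where the median of all genes was -0.27 and -0.39. Col7a1, the anchoring fibril collagen, was at 2.35 (SE 0.51) and Krt15, a keratin of follicle stem cells, at -4.35 (SE 1.38).

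Inflammatory cytokine and chemokine genes rose in the tumours, with 10 of 32 up and 0 down adjusted over the list alone (median 1.11, camera adjusted p = 0.000288, 0.422 with an estimated correlation). The keratinocyte-acting cytokine gene Il24 rose by 6.10 (SE 0.58) and its relative Il19 rose at least 57.0-fold, adjusted over the list alone. The epidermal chemokine genes Ccl27a and Cxcl14 had differences of -3.93 (SE 1.75) and -2.52 (SE 1.11). Neutrophil genes rose as a list, with 6 of 19 up and 2 down adjusted over the list alone (median 0.37, camera adjusted p = 0.0201, 0.422 with an estimated correlation). Its leading members, the stefin gene Stfa2l1 at 7.26 (SE 1.29) and S100a9 at 5.07 (SE 0.60), rose adjusted over the list alone, and S100a9 also stands in the hyperproliferative list. Without tumour 2 the cytokine and neutrophil calls were lost, at medians of 0.94 and 0.64, although 17 cytokine genes were then up and 9 down adjusted over the list alone. Those numbers were 16 and 3 without tumour 1, and 3 neutrophil genes rose and 0 fell without either SKO DMBA array. Without normalization between arrays, which moved the median of all genes to -0.39, the neutrophil median was -0.06. Over genes detected on all 6 arrays neither the cytokine (median 0.35) nor the neutrophil list (0.42) was called, and over every detected probe the neutrophil list was not called (0.35).

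Genes of cytosolic DNA sensing and STING signalling rose as a list, with 4 of 22 up and 0 down adjusted over the list alone (median 0.37, camera adjusted p = 0.00531, 0.422 with an estimated correlation). Ifi202b, a member of the interferon-inducible p200 family, rose by 3.44 (SE 0.61) and Samhd1, a nucleotide triphosphohydrolase, by 3.25 (SE 0.34), adjusted over the list alone. The count of 4 was 0 without either SKO DMBA array, and the median was -0.01 without normalization between arrays, where the median of all genes was -0.39. Interferon-stimulated genes were not called (median 0.20, camera adjusted p = 0.312) and 0 of 33 passed. Oas1g was at 2.16 (SE 0.53) and Ifi27l2a at -2.49 (SE 1.60). The interferon list was called upward without tumour 1 (median 0.82) and downward without tumour 2 (-0.56). With equal medians its median was -0.14, where the median of all genes was -0.27, and without normalization between arrays it was -0.26 and called upward relative to other genes. Of its genes 7 rose without tumour 1, and 2 rose and 11 fell without tumour 2, adjusted over the list alone. Macrophage and monocyte genes (median -0.72, camera adjusted p = 0.188), T and NK cell genes (0.26, 0.307) and antigen presentation genes (-0.76, 0.312) were not called. Without tumour 2 the macrophage (-1.57) and antigen presentation lists (-1.36) were called lower, and without tumour 1 the T and NK cell list (0.67) was called higher. Antigen presentation genes were also called lower over genes detected on all 6 arrays (-1.04), and both they (-0.86) and macrophage genes (-0.50) over every detected probe. Without tumour 2, 20 macrophage and 13 antigen presentation genes fell and 1 and 3 rose adjusted over the list alone, and without tumour 1, 10 T and NK cell genes rose and 1 fell. Arg1, an arginase of alternatively activated macrophages, was at 3.08 (SE 0.60) and Cd207, the Langerhans cell lectin, at -2.24 (SE 0.49). Mast cell genes (median -0.05, camera adjusted p = 0.859) and B cell and plasma cell genes (0.03, 0.987) were not called. In each, 1 gene rose adjusted over the list alone, the mast cell protease gene Mcpt1 at least 4.02-fold and Fcmr by 4.16 (SE 0.59), and 0 did without either SKO DMBA array. Without tumour 1, 4 mast cell genes rose and 3 fell, and without tumour 2 it was 2 and 4.

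Hypoxia and glycolysis genes rose, with 13 of 22 up and 0 down adjusted over the list alone (median 1.62, camera adjusted p = 1.53e-09, 0.422 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, rose by 3.67 (SE 0.26) and the glucose transporter gene Slc2a1 by 2.88 (SE 0.27), adjusted over the list alone. Cell cycle genes rose as a list, with 36 of 37 positive and a median of 0.87, although 0 passed alone (camera adjusted p = 1.38e-08, 0.639 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, was at 1.77 (SE 0.47). In the p53 target and DNA damage list, 4 of 27 rose adjusted over the list alone (median 0.60, camera adjusted p = 0.0158, 0.422 with an estimated correlation). Cdkn2a, which encodes cell cycle inhibitors and does not measure p53 activity, rose at least 20.8-fold and the BH3-only gene Pmaip1 by 2.34 (SE 0.36). The counts of both lists changed when single DMBA arrays were left out. The p53 target call was lost over genes detected on all 6 arrays (median 0.43) and with undetected signals raised to 1 limit for all arrays (0.60), a setting chosen after the data were seen.

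RAS-MAPK output genes and EGFR ligands rose as a list, with 8 of 24 up and 3 down adjusted over the list alone (median 0.84, camera adjusted p = 0.0304, 0.639 with an estimated correlation). The EGFR ligand genes Epgn and Hbegf rose by 3.74 (SE 0.53) and 3.26 (SE 0.58), and the immediate-early gene Egr1 changed by -1.42 (SE 0.33), adjusted over the list alone. Matrix proteases and invasion genes rose as a list, with 6 of 33 up and 1 down adjusted over the list alone (median 0.57, camera adjusted p = 0.0268, 0.639 with an estimated correlation). The stromelysin gene Mmp10 rose by 5.31 (SE 0.56) and the collagenase gene Mmp13 by 3.66 (SE 0.40), whereas the transcription factor gene Twist1 changed by -1.90 (SE 0.31), adjusted over the list alone. The RAS-MAPK call was lost without tumour 1 (median 0.42) and the protease call without tumour 2 (median 0.40), and over genes detected on all 6 arrays both were lost (0.84 and 0.55), as they were with undetected signals raised (0.46 and 0.55). Without either SKO DMBA array, 0 RAS-MAPK genes passed over the list alone, and 3 protease genes rose. Without tumour 2, 13 protease genes rose and 10 fell, and without tumour 1 it was 8 and 3. Xenobiotic metabolism genes of the AhR and NRF2 pathways were not called as a list (median 0.31, camera adjusted p = 0.312), but were called upward without tumour 2 (0.58) and, relative to other genes, without normalization between arrays (-0.20). Adjusted over the list alone 6 of 28 rose and 4 fell, among them the glutathione transferase gene Gsta4 with 6.07 (SE 0.93) and the cytochrome gene Cyp2e1, not detected in tumour 1, with -5.63 (SE 0.83). These counts were 10 and 11 without tumour 1, 13 and 6 without tumour 2, and 0 without either SKO DMBA array. Endothelium (median 0.08, mean -0.03, camera adjusted p = 0.728) and erythrocyte genes (0.59, 0.555) were not called, but endothelium was called upward without tumour 1 (0.43). By the test over the list alone, 2 endothelium genes rose without tumour 1, and 1 rose and 3 fell without tumour 2. With equal medians the xenobiotic (-0.08) and endothelium medians (-0.19) were negative.

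Markers of muscle, fat, hair, connective tissue, pigment cells, sebaceous gland and nerve fell as lists in the tumours. Skeletal muscle genes were negative in 33 of 33 cases with a median of -4.86, although 0 passed alone (camera adjusted p = 1.53e-09, 0.639 with an estimated correlation). Pvalb, the parvalbumin of fast muscle, was at -7.13 (SE 2.53) and not detected in tumour 1. Adipocyte genes were negative in 26 of 26 cases (median -2.68), and 10 fell adjusted over the list alone (camera adjusted p = 1.53e-09, 0.422 with an estimated correlation), a count that was 22 without tumour 1, 19 without tumour 2 and 6 without either SKO DMBA array. Adipoq, the adiponectin gene, was at -6.64 (SE 2.57) and not detected in tumour 1 either. With undetected signals raised, the muscle, hair and adipocyte medians were -4.37, -3.08 and -2.10. Hair shaft and follicle genes (median -3.64, camera adjusted p = 6.36e-06), fibroblast and matrix genes (-1.85, 3.76e-07) and melanocyte genes (-2.23, 0.00168) fell as lists with 0 members passing. Each had an adjusted p = 0.639 with an estimated correlation. Over genes detected on all 6 arrays, 5 of the hair and 6 of the melanocyte list, the hair (-2.58) and melanocyte calls (-1.56) were lost. Against WT acetone skin, the muscle, hair, fibroblast and melanocyte medians were -2.22, -1.50, -0.93 and -1.15 in tumour 2. In tumour 1, where most muscle and hair genes were not detected, they were -7.06, -5.50, -2.78 and -2.90. Sebaceous gland genes fell, with 5 of 22 down and 1 up adjusted over the list alone (median -1.0, camera adjusted p = 0.000641, 0.422 with an estimated correlation). They included the desaturase gene Scd1 with -2.98 (SE 0.72) and the lipid regulator gene Pparg with -2.72 (SE 0.35), and 0 passed without either SKO DMBA array but 11 fell without tumour 1 or 2, where 2 and 1 rose. Schwann cell and nerve genes fell as a list (median -2.05, camera adjusted p = 0.0342, 0.422 with an estimated correlation), a call that was lost with equal medians (-2.41) or no normalization between arrays (-2.53). Of its 9 members 0 passed, but 5 fell without tumour 1, and 7 fell and 2 rose without tumour 2.

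Across all 11997 genes, limma called 0 at an adjusted p under 0.05 in this comparison, and 1043 were higher and 1494 lower at an unadjusted p under 0.05, in all 2537 where chance alone gives 599.85 over both directions. The genes with the largest differences were Sprr2k (at least 503-fold higher, adjusted p = 0.0975), Lce3e (at least 196-fold, 0.0975), Sprr2i (at least 175-fold, 0.0947), Sprr2d (8.06, 0.111) and Lce3b (8.03, SE 0.83, 0.0975), all envelope genes. The largest fitted falls were those of the urinary protein gene Mup2 (-7.23, SE 2.99), the carbonic anhydrase gene Car3 (-7.18, SE 2.45), Pvalb, Serpina3b (-7.01, SE 1.52) and Hamp2 (at least 65.2-fold lower, adjusted p = 0.0947). Tumour 1 did not detect Mup2, Car3, Pvalb or Serpina3b, so the sizes and order of these falls were not measured, and with undetected signals raised they were -6.57, -6.44, -6.45 and -6.39. Both tumours lay above all 4 skin arrays for 3143 genes and below them for 3263, where chance gives 6.67% each (800 genes). The count of called genes was 527 without tumour 1 and 2840 without tumour 2, when the spread came from the SKO DMBA pair alone. Over all 27 lists, 120 list entries passed adjusted over the list alone, against 292 without tumour 1, 396 without tumour 2 and 59 without either SKO DMBA array. By fry, the sebaceous and neutrophil lists moved one way on balance (adjusted p = 0.0419 for each), and no list did in the other comparisons. The share of genes that were higher among those at an unadjusted p under 0.05 was 41.1%, but 22.5% with equal medians and 18.4% without normalization between arrays. In these settings the median of all genes was -0.27 and -0.39. Over genes detected on all 6 arrays the share was 52.2%, and with undetected signals raised 52.5%.

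**Figure D1:**
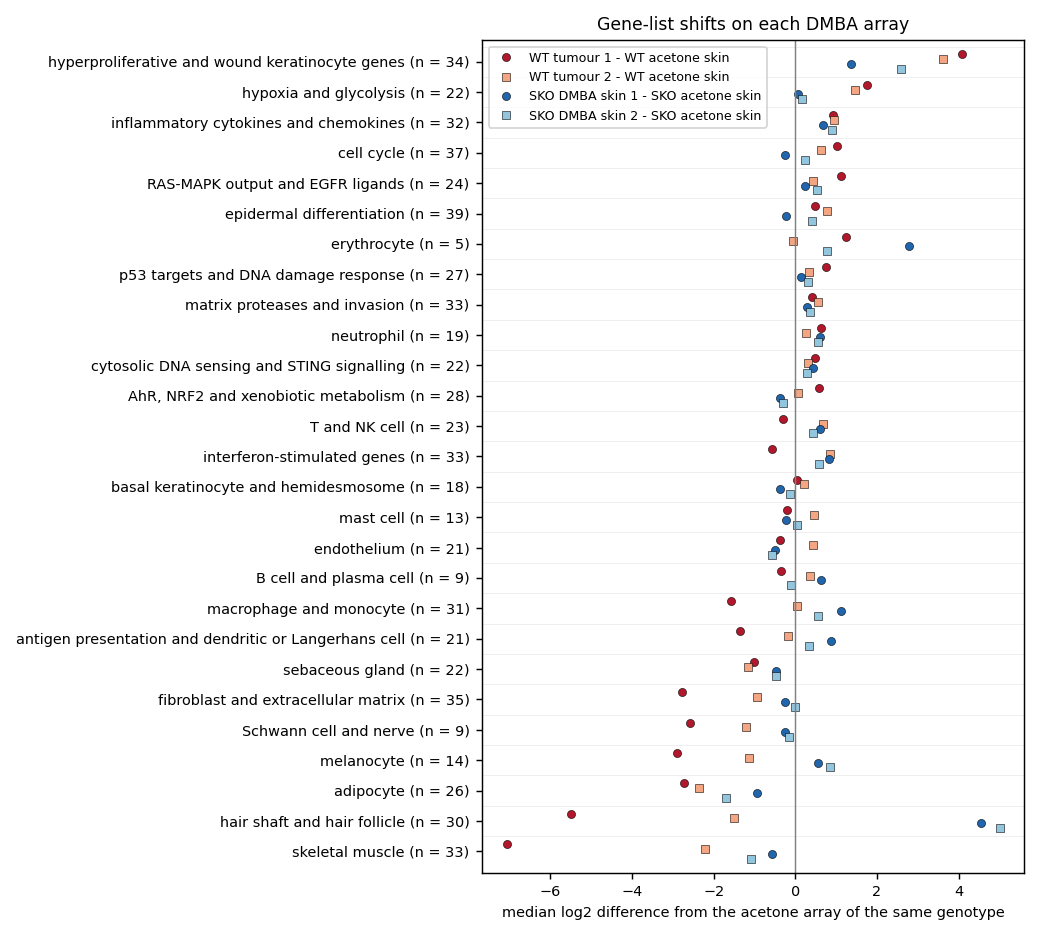
Median log2 difference over each gene list's measured genes (x axis; n is the number of genes) on each DMBA array, minus the acetone array of the same genotype; red and orange points are the WT tumours and blue points the SKO DMBA skins, with no error bar because each point is 1 array. The hyperproliferative keratinocyte list lies at 4.07 and 3.61 in the tumours, and the hair list lies at -5.50 and -1.50 in the tumours and to the right of 0 in both SKO DMBA skins.

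SKO skin treated with DMBA was compared with SKO acetone skin to find what DMBA painting changed where STING was absent and no tumour was sampled. Hyperproliferative and wound keratinocyte genes rose, with 33 of 34 positive and a median of 1.92. Adjusted over the list alone, 16 were up and 0 down (camera adjusted p = 7.69e-18, 0.479 with an estimated correlation). The envelope gene Sprr1b rose at least 61.5-fold and the stefin gene Stfa2 by 5.56 (SE 1.21), adjusted over the list alone. Several lists of immune genes rose. Of macrophage and monocyte genes 30 of 31 were positive (median 0.79, camera adjusted p = 0.000102), of interferon-stimulated genes 29 of 33 (0.71, 0.000111) and of T and NK cell genes 22 of 23 (0.57, 0.00103). Each of these lists had 0 members passing alone and an adjusted p = 0.643 with an estimated correlation. Without tumour 1 or tumour 2, 8 macrophage, 7 interferon-stimulated and 5 T and NK cell genes rose adjusted over the list alone, and 0 did without either SKO DMBA array. With undetected signals raised, the T and NK cell call was lost (0.50), and the count of 16 hyperproliferative genes was 4.

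Inflammatory cytokine and chemokine genes rose as a list in SKO DMBA skin (29 of 32 positive, median 0.50, camera adjusted p = 6.49e-05, 0.479 with an estimated correlation). Ccl4, which encodes a chemokine for monocytes and T cells, rose at least 4.62-fold adjusted over the list alone, and Ccl5 was at 2.16 (SE 0.72). The interferon-γ-inducible chemokine gene Cxcl9 was at 4.16 (SE 1.18) and Cxcl10 was at least 3.75-fold higher, neither passing. Antigen presentation genes rose as a list (median 0.58, camera adjusted p = 0.00253, 0.643 with an estimated correlation), as did cytosolic DNA sensing genes (0.31, camera adjusted p = 0.00439, 0.479 with an estimated correlation), where Samhd1 was at 1.25 (SE 0.34). Neutrophil genes rose as a list, with 4 of 19 up and 1 down adjusted over the list alone (median 0.73, camera adjusted p = 0.0404, 0.479 with an estimated correlation), and S100a9 rose by 3.00 (SE 0.60). The neutrophil call was lost without background correction (0.35), with an offset of 50 (0.33), on the authors' deposited matrix (0.35), without a filter or on the SKO arrays alone (0.73 in both), and without tumour 1 (0.77) or tumour 2 (0.73), and the antigen presentation call without SKO DMBA skin 1 (0.34). With undetected signals raised, the cytokine (0.40), antigen presentation (0.52) and neutrophil calls (0.13) were lost. Adjusted over the list alone, 11 cytokine genes rose without tumour 1 and 10 without tumour 2, but 0 without either SKO DMBA array, and 0 neutrophil genes passed without SKO DMBA skin 2. Without tumour 1, 7 neutrophil genes rose and 3 fell, and 2 antigen presentation genes rose without tumour 1 or tumour 2.

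Hair shaft and follicle genes rose in SKO DMBA skin relative to SKO acetone skin (27 of 30 positive, median 4.78, camera adjusted p = 9.76e-15, 0.479 with an estimated correlation), and 2 rose adjusted over the list alone, a count that was 25 without either tumour and 0 without either SKO DMBA array. The hair keratin genes Krt34 and Krt33b were at 7.52 (SE 2.69) and at least 118-fold higher. Against the WT acetone array in place of the SKO acetone array, a comparison chosen after the data were seen, the hair list had a median of 0.39 and was not called. Adipocyte genes fell (25 of 26 negative, median -1.32, camera adjusted p = 1.83e-09, 0.479 with an estimated correlation), with 5 down adjusted over the list alone. Nnat, the neuronatin gene, fell at least 8.79-fold. The count of 5 was 16 without either tumour and 0 without either SKO DMBA array. Sebaceous gland genes (median -0.53, camera adjusted p = 0.00399, 0.479 with an estimated correlation) and skeletal muscle genes (-0.79, camera adjusted p = 0.0107, 0.813 with an estimated correlation) fell as lists with 0 members passing, and the muscle call was lost without SKO DMBA skin 2 (-0.58) and over the 4 members detected on all 6 arrays (-0.60). Without tumour 1 or 2, 3 sebaceous genes fell adjusted over the list alone, and 5 and 6 muscle genes.

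Matrix protease genes rose as a list in SKO DMBA skin with 3 of 33 up adjusted over the list alone (median 0.31, camera adjusted p = 0.00399, 0.479 with an estimated correlation), among them the matrix gene Tnc with 2.31 (SE 0.41). In the p53 target and DNA damage list 3 of 27 rose adjusted over the list alone (median 0.22, camera adjusted p = 0.0107, 0.479 with an estimated correlation). They included Cdkn2a (at least 4.2-fold) and the kinase inhibitor gene Cdkn2b (1.86, SE 0.34), which do not measure p53 activity. RAS-MAPK genes rose as a list (0.33, camera adjusted p = 0.0342, 0.643 with an estimated correlation), a call that was lost without SKO DMBA skin 2 (0.23). The RAS-MAPK (0.25) and p53 target calls (0.032) were lost with undetected signals raised. Erythrocyte genes rose as a list, with 5 of 5 positive (median 1.77, camera adjusted p = 0.00253, 0.641 with an estimated correlation), led by the band 3 gene Slc4a1, at least 11.5-fold and adjusted over the list alone. Hypoxia and glycolysis genes were not called (median 0.13, camera adjusted p = 0.0694), but Egln3 rose by 2.34 (SE 0.26) and the carbonic anhydrase gene Car12 by 1.85 (SE 0.27) adjusted over the list alone. Without either SKO DMBA array, 0 protease, p53 target and hypoxia genes passed over the list alone, and the hypoxia list was called without SKO DMBA skin 1 (0.16). Without tumour 1 or 2, 6 protease, 4 hypoxia and 3 melanocyte genes rose by that test. Cell cycle genes were not called (-0.03, camera adjusted p = 0.804), but they were called upward without SKO DMBA skin 1 (0.23) and downward without SKO DMBA skin 2 (-0.24). Lists for endothelium (-0.43), melanocyte (0.72), basal keratinocyte (-0.24), B cell (0.34), epidermal differentiation (0.15), xenobiotic metabolism (-0.30), mast cell (-0.21), fibroblast (-0.18) and Schwann cell genes (-0.19, camera direction up) were not called. Calls appeared for endothelium without tumour 1 (-0.43), tumour 2 (-0.44) or SKO DMBA skin 1 (-0.58), for melanocyte genes without the same arrays (0.73, 0.72 and 0.82), and for epidermal differentiation without SKO DMBA skin 1 (0.41). They appeared for basal keratinocyte (-0.38) and B cell genes (0.64) without SKO DMBA skin 2, and over genes detected on all 6 arrays for endothelium (-0.53) and basal keratinocyte genes (-0.24), the latter also with equal medians (-0.23) or no normalization between arrays (-0.22). On the SKO arrays alone endothelium (-0.43) and melanocyte genes (0.72) were called, as they were over every detected probe (-0.43 and 0.42), and hypoxia genes were called over every probe (0.058) and without a filter (0.13).

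Across all genes limma called 0 at an adjusted p under 0.05 in SKO skin, and 476 were higher and 449 lower at an unadjusted p under 0.05, in all 925 against 599.85 by chance over both directions. The largest positive differences were in the hair shaft genes Krtap7-1 (at least 331-fold higher, adjusted p = 0.617), Krt34, Krt33b, Krtap26-1 (at least 94.9-fold) and Krtap6-2 (at least 94.6-fold). The largest fitted negative differences were in Hamp2 (-4.74, SE 0.45, adjusted p = 0.215), the retinol-oxidising dehydrogenase gene Adh7 (-4.25, SE 2.56, not detected in SKO DMBA skin 2), Mest (-3.85, SE 0.53), Cyp3a57 (at least 8.82-fold lower) and Nnat. Fitted on the 3 SKO arrays alone, limma called 201 genes, and it called 177 without tumour 1 and 202 without tumour 2. Over all lists, 38 list entries passed adjusted over the list alone, against 136 and 132 without tumour 1 or 2, and 18 and 14 without SKO DMBA skin 1 or 2. Against the WT acetone array, 10 of the 16 list calls were kept, and 0 hyperproliferative genes passed over the list alone in place of 16. The hair, sebaceous (-0.16), muscle (-0.31), neutrophil (0.12), RAS-MAPK (0.042) and protease (-0.32) calls were then lost, the last with its sign turned. Calls appeared in that comparison for 6 further lists, B cell (median 0.95), fibroblast (-0.43), endothelium (-0.42), basal keratinocyte (-0.26), hypoxia (0.19) and epidermal differentiation genes (0.085).

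WT tumours were compared with SKO DMBA skin, the tissues that DMBA painting left in each genotype. Keratinocyte wound genes and cell cycle genes rose in the tumours. Of 34 hyperproliferative genes 21 were up and 0 down adjusted over the list alone (median 3.14, camera adjusted p = 4.92e-11, 0.544 with an estimated correlation), and Sprr3, a small proline-rich protein gene of oral and oesophageal epithelium, rose at least 56.6-fold, with a log2 intensity of 13.98 in tumour 1 and 7.87 in tumour 2. Of 37 cell cycle genes 36 were positive and 12 rose adjusted over the list alone (median 0.86, camera adjusted p = 3.04e-08, 0.544 with an estimated correlation). Cdc20 rose by 1.76 (SE 0.38) and the topoisomerase gene Top2a by 1.62 (SE 0.38). The cell cycle count of 12 was 18 without tumour 2, and 0 without tumour 1, SKO DMBA skin 1 or SKO DMBA skin 2. It was also 0 with equal medians or without normalization between arrays, and 6 with undetected signals raised.

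Hypoxia and glycolysis genes rose in the tumours over SKO DMBA skin, with 15 of 22 up and 1 down adjusted over the list alone (median 1.51, camera adjusted p = 5.60e-08, 0.544 with an estimated correlation). Hif1a, the oxygen-regulated transcription factor gene, rose by 2.78 (SE 0.38) and Slc2a1 by 2.13 (SE 0.22), and the muscle-rich glycolytic gene Aldoa changed by -0.90 (SE 0.26). Inflammatory cytokine genes split, with 15 of 32 up and 4 down adjusted over the list alone (median 1.12, camera adjusted p = 0.0307, 0.544 with an estimated correlation). Il24 rose by 5.82 (SE 0.47) and Il19 by 5.55 (SE 0.75), whereas Ccl27a changed by -4.76 (SE 1.43). The cytokine call was lost without tumour 2 (median 0.94), over every detected probe (0.52), with undetected signals raised (0.43), and over genes detected on all 6 arrays, where the median was -1.01. Without SKO DMBA skin 1, 7 hypoxia genes, 1 cytokine gene and 1 protease gene rose adjusted over the list alone, and without SKO DMBA skin 2 it was 10, 10 and 5. Without tumour 2, 13 cytokine and 8 protease genes fell by that test. Matrix protease genes rose, with 10 of 33 up and 1 down adjusted over the list alone (median 0.58, camera adjusted p = 0.00398, 0.544 with an estimated correlation), among them Mmp10 at least 44.2-fold and Mmp13 by 5.26 (SE 0.32), and this call was lost without tumour 2 (0.57) and over genes detected on all 6 arrays (0.45).

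Genes of macrophages, antigen-presenting cells, B cells, T and NK cells and the interferon response fell as lists in the tumours relative to SKO DMBA skin, whereas neutrophil genes (median 0.38, 13 of 19 positive) and mast cell genes (-0.41) were not called. Of macrophage and monocyte genes 29 of 31 were negative and 0 passed (median -1.73, camera adjusted p = 1.04e-05, 0.571 with an estimated correlation). Of antigen presentation genes 8 of 21 fell and 2 rose adjusted over the list alone (median -1.51, camera adjusted p = 0.00306, 0.559 with an estimated correlation), where Cd207 changed by -2.90 (SE 0.40) and the costimulator gene Cd80 by 2.20 (SE 0.48). B cell and plasma cell genes fell, with 5 of 9 down and 1 up adjusted over the list alone (median -1.40, camera adjusted p = 0.00587, 0.544 with an estimated correlation), including the B cell receptor gene Cd79b with -2.50 (SE 0.54). Only 1 B cell gene was detected on all 6 arrays, Fcmr, at 1.53 (SE 0.48). T and NK cell genes (median -0.83, camera adjusted p = 0.00306, 0.571 with an estimated correlation) and interferon-stimulated genes (-0.91, camera adjusted p = 0.0111, 0.675 with an estimated correlation) fell as lists with 0 members passing, and the interferon-inducible GTPase gene Gbp2 was at -2.74 (SE 0.90). The T and NK cell and interferon calls were lost without tumour 1, at medians of -0.47 and -0.14, the T and NK cell call also over genes detected on all 6 arrays (-1.22), and the interferon call also with equal medians (-1.18) or no normalization between arrays (-1.28). The T and NK cell (-0.73) and B cell calls (-0.13) were lost with undetected signals raised. Without SKO DMBA skin 1, 0 antigen presentation and B cell genes passed over the list alone, and without SKO DMBA skin 2, 0 antigen presentation genes. Without tumour 2, 27 macrophage, 26 interferon-stimulated, 17 T and NK cell and 15 antigen presentation genes fell by that test, and without tumour 1, 14 macrophage and 4 T and NK cell genes, with at most 3 per list rising.

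Markers of muscle, hair, fat, connective tissue and pigment cells fell with them. Skeletal muscle genes were negative in 33 of 33 cases and 5 fell adjusted over the list alone (median -4.63, camera adjusted p = 5.60e-08, 0.559 with an estimated correlation). Hair genes (median -4.09, camera adjusted p = 3.22e-07) and adipocyte genes (-1.08, 0.00183) fell, each with an adjusted p = 0.544 with an estimated correlation, and fibroblast genes (-1.29, 0.000452) and melanocyte genes (-1.86, 0.00970) fell, each with an adjusted p = 0.635 with an estimated correlation. Over genes detected on all 6 arrays, again 5 of the hair and 6 of the melanocyte list, the hair (-3.14) and melanocyte calls (-1.70) were lost. The muscle, hair and adipocyte medians were -4.20, -3.43 and -0.44 with undetected signals raised. Sebaceous gland genes fell, with 9 of 22 down and 1 up adjusted over the list alone (median -0.69, camera adjusted p = 0.00658, 0.544 with an estimated correlation), among them Scd1 with -2.56 (SE 0.59) and the fatty acid amide hydrolase gene Faah with -2.44 (SE 0.50), and the call was lost without tumour 2 (-0.59). Without either SKO DMBA array 0 sebaceous and muscle genes passed, while 27 and 32 muscle, 26 and 28 hair, 14 and 12 adipocyte and 10 and 26 fibroblast genes fell without tumour 1 or 2, and 12 melanocyte genes without tumour 2.

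Of RAS-MAPK genes and EGFR ligands 7 of 24 rose and 1 fell adjusted over the list alone (median 0.77, camera adjusted p = 0.0247, 0.571 with an estimated correlation), with Epgn at 3.74 (SE 0.43) and Hbegf at 3.45 (SE 0.47). This call was lost without tumour 1 (0.23) or SKO DMBA skin 1 (0.43), with undetected signals raised (0.77), and over genes detected on all 6 arrays (0.79), and without tumour 2, 13 genes rose and 4 fell. Epidermal differentiation genes rose as a list, with 9 of 39 up and 4 down adjusted over the list alone (median 0.20, camera adjusted p = 0.0363, 0.675 with an estimated correlation). The transglutaminase gene Tgm3 rose by 4.95 (SE 0.83) and Krt77 changed by -5.45 (SE 0.90), and the call was lost without tumour 2 (0.15) or SKO DMBA skin 1 (-0.13), without a filter (0.20), with undetected signals raised (0.19), and over genes detected on all 6 arrays (0.31). Without SKO DMBA skin 1, 0 epidermal genes passed over the list alone, and without SKO DMBA skin 2, 4 rose. Lists for neutrophil (0.38, camera adjusted p = 0.0503), cytosolic DNA sensing (0.37, 0.0578), Schwann cell (-1.87, 0.0585), basal keratinocyte (0.26, 0.0700), p53 target (0.42, 0.0806), endothelium (0.36, 0.0503), xenobiotic metabolism (0.48, 0.260), erythrocyte (-0.12, 0.579) and mast cell genes (-0.41, 0.673) were not called. Calls appeared for neutrophil genes without tumour 1 (0.22), SKO DMBA skin 1 (0.46) or SKO DMBA skin 2 (0.28), and for DNA sensing (0.21 and 0.29) and Schwann cell genes (-0.57 and -1.94) without tumour 1 or 2. They appeared for endothelium without tumour 1 (0.80) or SKO DMBA skin 1 (0.48), for xenobiotic metabolism without tumour 2 (0.88), and for Schwann cell genes over genes detected on all 6 arrays (-1.98), on at least 2 arrays (-1.93) or without a filter (-1.87), on the mean of probes (-1.01) or every probe (-0.60), and with undetected signals raised (-1.19). Calls for DNA sensing (0.60) and endothelium (0.40) appeared over every probe and for p53 targets (0.40) on the mean of probes. With equal medians, basal keratinocyte (0.40) and neutrophil genes (0.13) were called, and without normalization between arrays these (0.31 and 0.031), DNA sensing (0.10), xenobiotic (0.21), p53 target (0.028) and endothelium genes (-0.030) were called upward relative to other genes. Single members passed over the list alone, among them Samhd1 with 2.04 (SE 0.28), Gsta4 with 5.94 (SE 0.76) and the mast cell protease gene Mcpt4 with -2.75 (SE 0.61). Of these lists, 0 RAS-MAPK, DNA sensing, basal keratinocyte, p53 target, xenobiotic and mast cell genes passed without either SKO DMBA array. Without tumour 1 or 2, 4 and 6 DNA sensing genes rose, 6 and 1 endothelium genes rose and 0 and 1 fell, and of xenobiotic genes 9 and 13 rose and 11 and 6 fell.

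Across all genes limma called 0 at an adjusted p under 0.05 between tumours and SKO DMBA skin, and 1489 were higher and 2044 lower at an unadjusted p under 0.05, in all 3533 against 599.85 by chance over both directions. The largest fitted positive differences were in Sprr2k (9.07, SE 0.68, adjusted p = 0.0698), Sprr2i (6.84, SE 0.43, 0.0584), the mucosal keratin gene Krt13 (at least 58.3-fold higher, 0.212, with a log2 intensity of 15.34 in tumour 1 and 6.60 in tumour 2), Sprr3 and Csta3 (6.32, SE 0.81, 0.0716). The largest fitted negative ones were in Pvalb (-6.73, SE 2.07), the lipoxygenase gene Alox12e (-6.37, SE 1.04, adjusted p = 0.0798), the muscle genes Myl1 (-6.32, SE 3.00) and Acta1 (-6.27, SE 3.00), and the follicle keratin gene Krt71 (-6.32, SE 2.80). Tumour 1 did not detect any of these 5, nor Krt77 or Cd79b, and SKO DMBA skin 1 did not detect Sprr2k, Il24, Il19, Tgm3 or Cd80, so the sizes and order of their differences were not measured. With undetected signals raised, the differences were -6.05 for Pvalb, -6.16 for Alox12e, -5.69 for Myl1, -5.60 for Acta1 and -5.73 for Krt71. The count of called genes was 898 without tumour 1, 3746 without tumour 2, 135 over genes detected on all 6 arrays, 7 without background correction, 7 on the authors' deposited matrix and 9 on the mean of a gene's probes. Over all lists, 171 list entries passed adjusted over the list alone, against 284 and 448 without tumour 1 or 2, and 29 and 61 without SKO DMBA skin 1 or 2. The higher share at an unadjusted p under 0.05 was 42.1%, 25.3% with equal medians, 20.5% without normalization between arrays and 52.6% over genes detected on all 6 arrays. Equal medians and no normalization moved the median of all genes to -0.24 and -0.33.

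**Figure D2:**
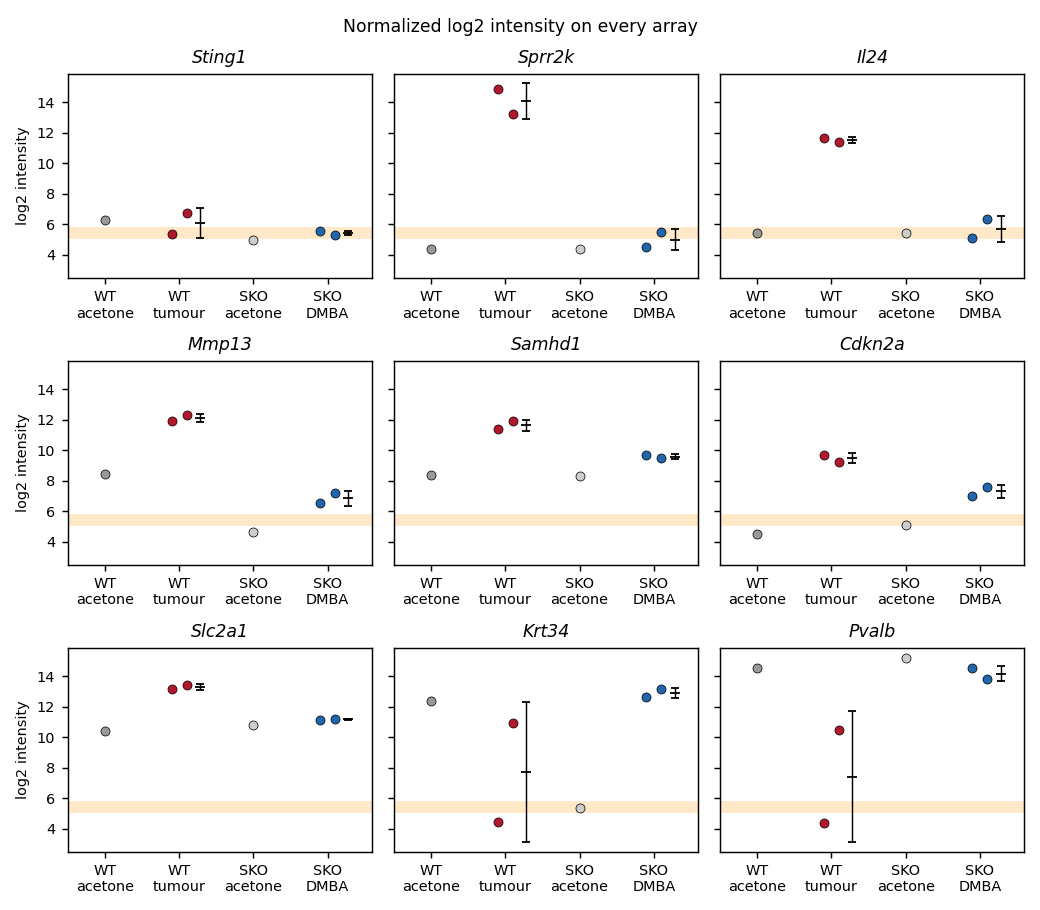
Normalized log2 intensity (y axis) of 9 genes on each of the 6 arrays; points are arrays, bars show mean and SD of the groups of 2, and the shaded band spans the lowest detected signal of the arrays. Pvalb is at 4.37 in tumour 1 and 10.47 in tumour 2, and Krt34 at 4.46 and 10.95, neither detected in tumour 1, whereas Slc2a1 is at 13.16 and 13.41. Krt34 is at 5.38 in SKO acetone skin.

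The difference between the responses, WT tumour minus WT acetone skin against SKO DMBA skin minus SKO acetone skin, was tested for each list and gene. Hair genes had the largest list difference. All 30 of 30 were more negative in WT, with a median difference of responses of -8.83, and 21 passed adjusted over the list alone (camera adjusted p = 3.68e-18, 0.729 with an estimated correlation). Krt34, not detected in tumour 1, had a fitted difference of -12.21 (SE 3.80). The count of 21 was 0 without either SKO DMBA array and 1 with undetected signals raised, where the hair median was -7.97. Relative to WT acetone skin, the hair median was -4.13 on the SKO acetone array, and -5.50 and -1.50 on the tumours. Cell cycle genes (median 0.91, 36 of 37 positive, camera adjusted p = 7.68e-09) and hypoxia and glycolysis genes (1.35, 19 of 22, 7.68e-09) responded more in WT, each with an adjusted p = 0.729 with an estimated correlation. Slc2a1 differed by 2.52 (SE 0.38) adjusted over the list alone. The WT response was also higher in hyperproliferative (median 1.47, camera adjusted p = 0.00405) and epidermal differentiation genes (0.25, 0.00667), each with an adjusted p = 0.729 with an estimated correlation, and Rptn differed by 4.19 (SE 0.50) adjusted over the list alone. It was lower in fibroblast (-1.72, 3.10e-06), skeletal muscle (-3.84, 6.51e-06), macrophage (-1.70, 0.000127), melanocyte (-2.53, 0.000127), antigen presentation (-1.39, 0.00459) and adipocyte genes (-1.03, 0.0450), again each with an adjusted p = 0.729 with an estimated correlation. With undetected signals raised, the hyperproliferative (1.75), epidermal (0.25) and adipocyte calls (-0.37) were lost. Without SKO DMBA skin 1 the epidermal (0.04) and adipocyte (-0.73) calls were lost, and over genes detected on all 6 arrays the hyperproliferative (1.17), melanocyte (-1.63) and adipocyte calls (-0.29). With equal medians or without normalization between arrays the antigen presentation (-1.46 and -1.59) and adipocyte calls (-1.26 and -1.39) were lost, the latter also with an offset of 50 (-0.58) and over genes detected on at least 2 arrays (-1.20). Without tumour 2, 31 muscle, 26 macrophage, 25 fibroblast, 12 antigen presentation, 12 melanocyte and 11 adipocyte genes passed as more negative in WT over the list alone, and 15 hypoxia, 14 hyperproliferative and 9 epidermal genes as more positive, with at most 3 per list the other way. Without tumour 1, 12 muscle and 7 melanocyte genes were more negative, and 10 hyperproliferative and 6 epidermal genes more positive, with at most 5 per list the other way.

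The other lists were not called different between the genotypes at the settings used above. The cytokine list had a median of -0.16, a mean of 0.18 and a camera adjusted p of 0.208, and camera placed it upward. Adjusted over the list alone, Il24 differed by 5.84 (SE 0.82), and so did Il33, an epithelial alarmin gene chosen after its values were seen, by 3.28 (SE 0.56). Median and camera adjusted p were -0.83 and 0.121 for interferon-stimulated, 0.17 and 0.194 for DNA sensing, -0.34 and 0.187 for T and NK cell, -0.25 and 0.470 for neutrophil (mean 0.24), and 0.33 and 0.194 for RAS-MAPK genes. They were 0.07 and 0.327 for p53 target, 0.22 and 0.642 for protease, 0.55 and 0.0512 for basal keratinocyte, -1.92 and 0.0545 for Schwann cell, and -0.42 and 0.106 for sebaceous genes. They were 0.17 and 0.123 for endothelium, 0.76 and 0.123 for xenobiotic metabolism, -0.34 and 0.163 for erythrocyte, -0.45 and 0.329 for B cell, and 0.01 and 0.600 for mast cell genes.

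Without tumour 2 the interferon (-1.47), T and NK cell (-1.10), xenobiotic (1.38), RAS-MAPK (0.70) and Schwann cell lists (-2.47) were called different between the genotypes, and 18 interferon and 7 T and NK cell genes passed as more negative in WT over the list alone. Without tumour 1 the Schwann cell (-0.79), endothelium (0.55), erythrocyte (-1.30) and sebaceous lists (-0.55) were, and without SKO DMBA skin 2 the basal keratinocyte (0.67) and erythrocyte lists (-1.21). The interferon (-0.89), sebaceous (-0.74), xenobiotic (0.98) and Schwann cell lists (-1.92) were over genes detected on all 6 arrays, and the 1 B cell gene left. Schwann cell genes were also called without background correction (-1.41), on the authors' deposited matrix (-1.41), with an offset of 50 (-1.57), with undetected signals raised (-1.91), without a filter (-1.92) and over genes detected on at least 2 arrays (-1.92). Basal keratinocyte genes were called without background correction, on that matrix (0.54 in both), over genes detected on at least 2 arrays (0.55), with equal medians (0.66) and without normalization between arrays (0.54). Sebaceous genes were called without a filter (-0.42) and over every probe (-0.34), as were interferon (-0.68), DNA sensing (0.35), T and NK cell (-0.41) and erythrocyte genes (-0.70) over every probe. Xenobiotic genes were called with equal medians (0.49) and without normalization (0.36), and in the latter setting cytokine (-0.59) and RAS-MAPK genes were placed upward relative to other genes. Without normalization between arrays the medians of DNA sensing (-0.27), endothelium (-0.31), p53 target (-0.35), protease (-0.27) and RAS-MAPK genes (-0.08) were negative, and the median of all genes was -0.45. Limma called 0 genes at an adjusted p under 0.05, and 413 were positive and 542 negative at an unadjusted p under 0.05, in all 955 against 599.85 by chance over both directions. The largest fitted positive differences of responses were in Sprr2k (adjusted p = 0.405), Sprr2i, Krt13, Sprr3 and Gsta4, and the largest negative ones in Krtap7-1, Krt34, Krt33b, Krtap6-2 and Krtap2-4. Of these, Gsta4 (6.25, SE 1.32) was detected on every array. Krt34 was not detected in tumour 1, and the others not in at least 1 of the groups, so their order and the sizes of their differences were not measured. The count of called genes was 131 without tumour 1 and 1241 without tumour 2. Of all list entries 34 passed adjusted over the list alone, against 117 and 321 without tumour 1 or 2, and 1 and 7 without SKO DMBA skin 1 or 2. The share of positive genes at an unadjusted p under 0.05 was 43.2%, 25.1% with equal medians, where the median of all genes was -0.32, 20.2% without normalization, 54.6% over genes detected on all 6 arrays and 59.8% with undetected signals raised.

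At an unadjusted p under 0.05 in each response, 131 genes were higher in both genotypes and 251 lower in both, where independent lists of those sizes share 41.4 and 55.9. In opposite directions, 9 genes were higher in WT and lower in SKO, and 59 the reverse, where independent lists share 39.0 and 59.3. Both tests used the same estimate of each gene's spread, so independent lists do not give the value for no change. In 20 simulated sets of unchanged arrays, 60.6 genes on average passed in the same direction and 59.4 in opposite directions, where independent lists share 15.2 in the same direction. The observed totals were 382 in the same and 68 in opposite directions, and the simulation leaves out real effects, so the excess over it is not a count of shared effects. Across all genes the responses correlated with r = 0.213 and Spearman's rho = 0.323, which describes genes and not replicates. The comparisons shared no array. The total of 382 was 758 without tumour 1, 853 without tumour 2, 200 without SKO DMBA skin 1 and 117 without SKO DMBA skin 2.

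SKO acetone skin was set against WT acetone skin to show how the genotypes differed without DMBA, with 1 array each and therefore no replicate check or test. Hair genes lay lower in SKO (29 of 30, median -4.13, percentile 0 of random lists), as did melanocyte (-1.13, percentile 0), hyperproliferative keratinocyte (-0.88, percentile 0), neutrophil (-0.45, percentile 0), fibroblast (27 of 35 lower, median -0.35, percentile 0), matrix protease (-0.27, 0.04) and RAS-MAPK genes (-0.18, 2.15). SKO acetone skin did not detect 13 of the hair genes, and with undetected signals raised the hair median was -3.69 and the interferon median 0.097. Interferon-stimulated genes (0.30, percentile 99.96), macrophage genes (0.29, 99.99), T and NK cell genes (0.31, 99.7), B cell genes (0.55, 99.71) and skeletal muscle genes (0.42, 100) lay higher. So did antigen presentation (0.24, 99.01), xenobiotic metabolism (0.26, 99.72), adipocyte (0.20, 98.86) and sebaceous genes (0.21, 98.61). DNA sensing genes (-0.10, 10.7), cytokine genes (-0.07, 12.5) and the lists not named here lay within the central 95% of random lists. Of all genes 273 were over 2-fold higher and 420 over 2-fold lower in SKO. Highest relative to WT were Adh7 (at least 95.6-fold higher), Tm7sf3 (at least 19.1-fold), Lrrc57 (at least 10.2-fold), the cone opsin gene Opn1mw (at least 8.60-fold) and Nudt6 (3.26). Lowest were the hair genes Krtap7-1 (at least 227-fold lower), Krtap6-2 (at least 77.6-fold), Krt34 (-7.02) and Krt33b (at least 70.3-fold).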

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

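The tests of what separated the tumours from each other and of the hair genes in SKO skin were chosen only after those results were seen, whereas the tests of the gene lists were fixed beforehand.

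The response to DMBA differed between the genotypes in 11 gene lists by the camera test of the difference of responses. With an estimated correlation none held, at an adjusted p of 0.729 for each. WT samples were tumours and SKO samples were skin, so the differences cannot be assigned to STING. The median difference, WT response minus SKO response, was -8.83 for hair, -3.84 for skeletal muscle, -2.53 for melanocyte, -1.72 for fibroblast and -1.03 for adipocyte genes. It was -1.70 for macrophage and -1.39 for antigen presentation genes, where the WT medians were -0.72 and -0.76 and the SKO medians 0.79 and 0.58. It was 0.91 for cell cycle, 1.35 for hypoxia and glycolysis, 1.47 for hyperproliferative keratinocyte and 0.25 for epidermal differentiation genes. Cell cycle genes had medians of 0.87 in WT and -0.03 in SKO, and hypoxia genes 1.62 and 0.13.

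Relative to tumour 1, tumour 2 had higher medians of muscle (4.76), hair (3.97), melanocyte (1.71), T and NK cell (1.61), interferon-stimulated (1.58), macrophage (1.54), nerve (1.51) and fibroblast genes (1.46), although 2 of 9 nerve genes, 1 of 33 interferon-stimulated genes and 1 of 31 macrophage genes were over 2-fold higher in tumour 1. Acetone-like skin mixed into tumour 2 could raise such genes only up to their level in skin. Of the 1240 genes over 2-fold higher in tumour 2, 8.79% exceeded WT acetone skin by over 2-fold, which argues against mixing for those only. For the 591 genes over 2-fold higher in tumour 1, dilution needs a skin share of 50%, and the muscle, hair, melanocyte, nerve and fibroblast lists implied medians of 18.5% (muscle) to 39.3% (melanocyte) with upper quartiles of at most 47.9%, which narrowly argues against dilution by these tissues. A single share is also argued against, narrowly, since the quartile ranges of the muscle and fibroblast lists (medians 18.5% and 33.1%) lay 2.14 percentage points apart, while unequal admixture of skin layers stays open for the tissue markers. Array scaling is argued against, because at least 308 genes differed by over 2-fold in the rarer direction under 3 normalizations, above the bound of 195, and a biological difference between the tumours stays open as untested.

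Hair genes were higher in SKO DMBA skin than in SKO acetone skin by a median of 4.78, and this list had the largest difference between the genotypes. A candidate explanation is a low hair keratin level on the single SKO acetone array: against WT acetone skin, SKO DMBA skin had a median of 0.39, and its arrays lay at 0.27 and 0.63, whereas SKO acetone skin lay at -4.13. Tumour 1 at -5.50 and tumour 2 at -1.50 add to the difference. Whether the SKO acetone sample was in another phase of the hair cycle, came from another site, or was low in hair through the loss of STING was not tested and stays open with 1 array.

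Among the 10396 probes without exactly 1 listed gene, which entered no comparison, 20 were detected on both tumours and on no skin array, which is 0.624% of those detected at all, where it was 146 (0.781%) among probes with 1 gene. In the same set 37 (1.16%, against 0.813%) were detected on both SKO DMBA skins alone and 172 (5.37%, against 6.02%) on both acetone arrays and neither tumour.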

How the results depend on the processing

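The WT acetone control in SKO skin and the raising of undetected signals were chosen after the data were seen. Of the list results under alternatives, 1934 kept direction and side of the threshold and 117 passed it only there. Another 77 no longer passed, 70 moved without a call and 6 reversed. Camera uses no eBayes option or fold minimum, so those settings repeat the main calls. The number of called genes in WT tumours against WT acetone skin was 57 at an adjusted p under 0.10 in place of 0, and 0 to 2840 without 1 array. In SKO skin it was 201 when the SKO groups were fitted alone, and 0 to 202 without 1 array. Between tumours and SKO DMBA skin it was 7 without background correction, 7 on the authors' matrix, 135 over genes detected on all 6 arrays, 9 on the mean of probes and 1218 at an adjusted p under 0.10, and 0 to 3746 without 1 array. For the difference of responses it was 0 to 1241. Without a tumour the spread rests by construction on the SKO DMBA pair alone, which differed less than the tumours; the cause of the other moves was not tested. With an estimated correlation 0 lists were called in each comparison, in place of 17, 16, 18 and 11. Over genes detected on all 6 arrays 11 lists were called in each of the 2 tumour comparisons, of which 10 kept their direction from the 17 and 18 and 1 was added in each; in SKO skin 15 of 16 and in the difference of responses 8 of 11 were kept. Of the hyperproliferative list, 40 probes passed over the list alone in tumours against WT acetone skin and 35 against SKO DMBA skin when every detected probe was tested, where more members are counted by construction. In SKO DMBA skin 0 passed against the WT acetone array and 4 with undetected signals raised. That setting kept 14 of the 17 list calls in tumours against WT acetone skin, 10 of 16 in SKO skin, 13 of 18 between tumours and SKO DMBA skin and 8 of 11 in the difference of responses; by construction it removes spread and difference among undetected signals. Sting1 turned sign there in SKO skin (-0.30) and in the difference of responses (0.26). Genes over 2-fold apart between the acetone arrays numbered 366 without background correction and on the authors' matrix, 436 with an offset of 50, 296 over genes detected on all 6 arrays and 1218 over every detected probe, in place of 693. The overlap of the responses was 633 without a filter, 245 over genes detected on all 6 arrays, 596 over every detected probe, and 117 to 853 without 1 array. Reversals without 1 array that involved a call, or Sting1, were the interferon list in tumours against WT acetone skin (-0.56 to 0.82), cell cycle genes in SKO skin (-0.24 to 0.23), and Sting1 in tumours against WT acetone skin (-0.91 to 0.48) and SKO DMBA skin (-0.046 to 1.37). Medians without a call in that setting also turned sign, among them epidermal genes between tumours and SKO DMBA skin without SKO DMBA skin 1 (-0.13), and in tumours against WT acetone skin T and NK cell (-0.31) and endothelium genes (-0.38) without tumour 2 and macrophage genes (0.05) without tumour 1. Over genes detected on all 6 arrays the cytokine median between tumours and SKO DMBA skin was -1.01, and the B cell list was left with 1 gene, at 1.53 there and 4.14 in the difference of responses. Against the WT acetone array, SKO DMBA skin had -0.32 for protease genes, -0.86 for Sting1 and 3.16 for Adh7, the last a fitted value and no measured size, because the WT acetone array did not detect Adh7. Signal under the detection limit on 2 arrays limits Sting1, and it limits every gene given as a bound or as not detected on 1 array. No paired analysis was possible, as replicate numbers only follow accession order.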

Other observations

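All tests in this part except that of gene pairs within 10 genes of each other were chosen only after the results were seen, and so were the genes named.

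Some of the genes furthest above tumour 2 in tumour 1 were not detected in WT acetone skin. Krt13, a keratin of oral and oesophageal epithelium, had a log2 intensity of 15.34 in tumour 1 and 6.60 in tumour 2, and the tight junction gene Cldn17 11.76 and 7.83, and no skin array detected either. Bpifa5, of the secreted BPI fold family, was at 12.02 in tumour 1 and was detected on no other array. Krt4, the partner keratin gene of Krt13, was at 10.17 in tumour 1 and was detected neither in tumour 2 nor in acetone skin, but in both SKO DMBA skins. The glutathione transferase gene Gsta2, which all arrays detected, was at 13.62 in tumour 1, 9.41 in tumour 2 and 7.05 in WT acetone skin. With 1 array for each tumour these values have no replicate.

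Among genes that tumour 2 and WT acetone skin detected, Cxcl9 was 2.78 higher in tumour 2, the DNA sensor gene Aim2 2.76 and Oas1g 2.73, without a test.

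Genes over 2-fold apart between all 3 SKO and all 3 WT arrays numbered 43, 29 higher and 14 lower in SKO. Gramd4 was at least 4.66-fold and Lrrc57 at least 6.88-fold higher in SKO, and Rmdn3 and Tomm22, detected on all arrays, were 2.89 and 2.30 higher. Snx5 was at least 4.73-fold, Plet1 at least 4.13-fold and Cxcl2 at least 5.75-fold lower in SKO. Adamts9 was at -3.20 and Mmp13, which 2 of the 3 SKO arrays detected, at -4.77. Of the 10 splits of the 6 arrays into groups of 3, the highest other split gave 73, and the splits are too few for a share under 0.05.

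Inherited chromosome segments are a candidate explanation for these genes, since the mice were of a mixed C57BL6/129Sv background, although none of the 42 with a known place lay on the chromosome of Sting1. Pairs whose symbols begin with the same letters, such as Cxcl1 and Cxcl2, were not counted, here or in the random sets. Of the pairs counted, 1 (Lrrc57 and Ccndbp1) lay within 10 genes of each other, where random sets averaged 0.450. Within 200 genes lay 12 pairs, where random sets averaged 7.36 (percentile 92.1). The count within 10 genes lies within the lower 95% of random sets, which by the criterion written before it was known would speak against segments. It is left open because its counting limits of 0.0253 to 5.57, considered only after it was seen, pass the 95th percentile of 2. The count within 200 genes had no prior criterion. Its counting limits of 6.20 to 20.96 pass the 95th percentile of 12, so it is left open too. An effect of STING loss itself was not tested.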
